A study of Mus musculus with 6 samples.

How the data were processed

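The samples were primary macrophages from WT mice and from mice labelled METRNL knockout, each cultured with *Candida albicans* for 6 h, with 3 libraries per genotype. Groups and replicate numbers were taken from the sample titles. Per the labels, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq kit. The labels' extraction text speaks of retinas while all other labels name macrophages, so a list of retinal markers was included. The genome build was GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting tool, the annotation release and whether counting used strand are not given in the sources used here.

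The authors deposited 1 table of FPKM values with 54532 Ensembl genes, their coordinates, lengths, descriptions and transcription factor families. Of these identifiers 54409 were in the GENCODE M21 annotation of GRCm38, 53499 with the same start and end. The deposited FPKM multiplied by the deposited gene length was a whole multiple of 1 step per library for 100% of values above 0, within 0.05 of a step. The multiples were taken as reads. The per-million totals that the steps imply differed from the summed reads by factors equal to median-of-ratios size factors (largest relative difference 4.1e-11). The FPKM therefore carry that library scaling, and their sums differ between libraries, from 311409 to 412048. Reads in genes ranged from 11026529 to 15724897 per library. The 10 most read genes took 10.5% to 13.7% of the reads.

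Replicates were compared by a chi-square of recovered reads over genes with at least 20 reads in a pair. The ratio of chi-square to its degrees of freedom was lowest for KO replicates 2 and 3, at 2.30, and was 7.10 for WT replicates 2 and 3. Other pairs of the same group lay between 39.6 and 59.4. A ratio of 1 is sampling noise alone. All pairs lay above it, and all 6 libraries were used as separate replicates. Separate preparations of one culture would also lie above 1, so the ratios do not show that replicates came from separate cultures.

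Tests used limma 3.58.1 in R 4.3.3. FPKM is not a count, so values were analysed as log2(FPKM + 1) for 11689 genes with a mean of at least 0.5 FPKM over all 6 libraries. The linear model held genotype alone, with eBayes and an intensity trend, and Benjamini-Hochberg adjusted p below 0.05 was called. Log2 fold changes are KO minus WT on the log2(FPKM + 1) scale, which understates changes of low genes, while folds are ratios of mean FPKM. Where a group had no reads, the fold is a bound with 3 reads over the group. Intervals and floors cover counting error or the spread of these libraries only. Gene symbols with several rows take the row with the highest mean.

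Lists of genes, 50 in all, covering pathways, RNA quality, sample checks and other cell types were fixed before the data were examined. The 43 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation and with fry. Transcription factor families with 10 to 300 tested members were tested with camera at the preset and the estimated correlation, but not with fry. Each list also has counts adjusted over the list alone.

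Named genes followed a rule fixed before the data were examined. It takes *Metrnl* and *Metrn*, and the 12 largest rises and 12 largest falls among called genes with groups that do not overlap, a mean of at least 2 FPKM in the higher group and a symbol that is not a predicted gene. It adds up to 4 members with the smallest p from each called list and from the cytokine, chemokine, fungal receptor and fungal killing lists. From called lists of cell types or RNA quality it adds up to 3 members with the highest mean. Not every gene that the rule takes is reported here. Genes named outside the rule are said to be chosen after their values were seen.

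Scripts were tested on simulated data: reads drawn for the real genes and library sizes with a dispersion of 0.02 and 200 genes changed between KO and WT. Of the changed genes among 11677 tested, 59.4% of those changed 2-fold and 96.8% of those changed 4-fold were called in the right direction, with 13 false calls among 162. A simulated list of raised genes was called and 0 of 100 unchanged lists were. The simulated genes were drawn independently of each other, while the type I interferon list had an estimated correlation of 0.89. The 0 therefore does not give the rate of false calls for lists of correlated genes. The dispersion was set, not estimated, and was the same for all genes and libraries. Real pairs of the same group had chi-square ratios from 2.30 to 59.4. The shares recovered and the false calls therefore do not give rates for these libraries.

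Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a mean of at least 2 FPKM, quantile normalization, median-of-ratios factors on FPKM, TPM, robust eBayes, eBayes without the trend, array weights, the replicate number as a block, each library left out, other thresholds and the other list tests. Others were added after seeing the data: voom on the recovered reads, both replicate 1 libraries left out, and TPM with the filter kept on FPKM. Other tests for read counts were not used, since the deposited table holds FPKM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.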

Results

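RNA was sequenced from primary macrophages of wild-type (WT) mice and of mice labelled as knockouts (KO) of *Metrnl*, the gene of the secreted protein meteorin-like. Both sets of cells had been cultured with the fungus *Candida albicans* for 6 h before RNA was taken. There were 3 WT and 3 KO libraries. The deposited values are FPKM, fragments scaled for gene length and library size, for 54532 genes, of which 28477 had at least 1 read in any library. The reads behind these values could be recovered as whole numbers. They came to 14309247, 11026529 and 12458673 reads in genes for WT replicates 1 to 3 and to 14772746, 15724897 and 14915816 reads for KO replicates 1 to 3. The design holds one comparison, KO against WT in infected cells, and no uninfected libraries. It therefore addresses how gene activity during the fungal challenge differs with the *Metrnl* genotype, not the response to the fungus. The labels do not say whether replicates were separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

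*Metrnl* itself (ENSMUSG00000039208, chromosome 11, 121701544 to 121716306, GRCm38, plus strand, protein coding) kept its RNA in the KO-labelled libraries. Its values were 93.5, 63.2 and 69.8 FPKM in WT replicates 1 to 3 and 51.2, 63.6 and 62.8 FPKM in KO replicates 1 to 3. The group means were 75.5 ± 15.9 FPKM (SD, n = 3) in WT and 59.2 ± 6.95 FPKM (SD, n = 3) in KO. The log2 fold change, KO minus WT, was -0.33 ± 0.16 (SE) with a 95% confidence interval of -0.73 to 0.06, and it did not pass the threshold (limma, adjusted p = 0.181). The paralogue *Metrn* was at 0 FPKM in 5 of the 6 libraries and at 0.0884 FPKM in KO replicate 2. A per-gene value counts reads from any part of the gene and cannot show which exons were present. *Metrnl* RNA therefore does not check the genotype labels, and KO below means the libraries labelled KO in every stated direction.

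The KO and WT libraries differed widely. Of 11689 genes tested, 1833 were higher and 1445 were lower in KO (limma, Benjamini-Hochberg adjusted p below 0.05). Of these, 126 of the higher and 405 of the lower genes differed by at least 2-fold on the log2(FPKM + 1) scale, so the large differences were mostly lower values in KO. The 3 KO values all lay above or all below the 3 WT values for 5326 genes, 45.6% of those tested, where chance gives 10% on average. Genes that vary together can put a single split of the libraries far from that average, so this comparison is not a test. The first principal component carried 63.4% of the variance and parted the genotypes. The second carried 17.9% and set WT replicate 1 and KO replicate 1 apart from the other libraries of their groups, on opposite sides. Rescaling to TPM, in which each library sums to the same total, gave 511 higher and 1324 lower genes among 15259 that passed the filter in TPM, a share of higher calls of 27.8% against 55.9% with the deposited scaling. In TPM over the same 11689 genes, an alternative chosen after seeing the data, 542 were higher and 1161 lower, a share of 31.8%. Leaving out 1 library lowered the counts most for WT replicate 2 (1161 higher, 930 lower), WT replicate 3 (1053 and 849), KO replicate 2 (911 and 865) and KO replicate 3 (908 and 867), and leaving out both replicate 1 libraries, an alternative chosen after seeing the data, gave 2260 and 1914. The libraries that then remained were the most alike pairs of their groups, which lowers the spread that the test uses.

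**Figure D1:**
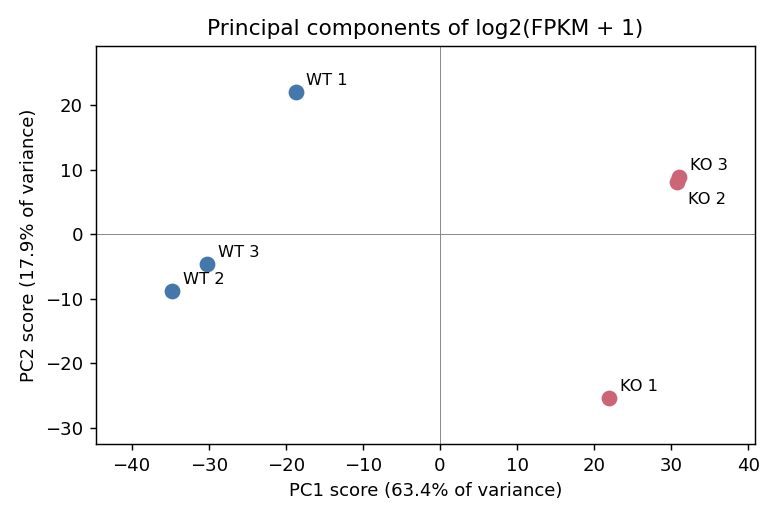
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1) over the 11689 tested genes, WT in blue and KO in red. The horizontal axis (63.4% of variance) parts the genotypes, and WT 1 and KO 1 lie away from the other libraries of their groups on the vertical axis (17.9%).

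**Figure D2:**
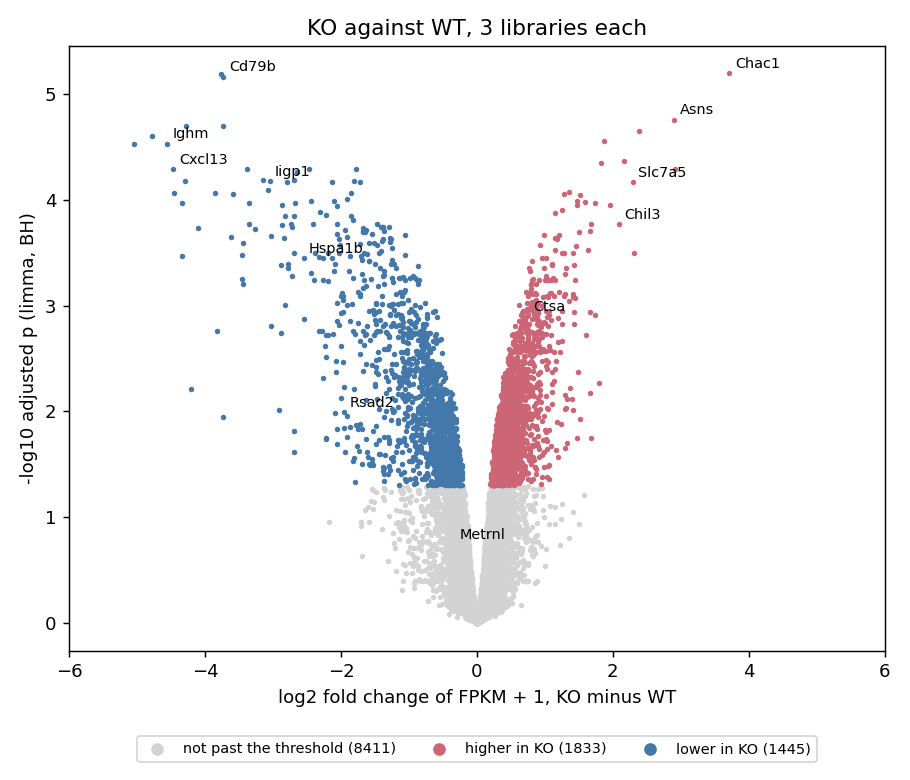
Log2 fold change (KO minus WT, horizontal) against −log10 adjusted p from limma (vertical), 1 point per tested gene. Red points are the 1833 genes higher in KO, blue points the 1445 lower, and *Metrnl* lies among the genes that did not pass.

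Of the 12 genes with the largest rise in KO on the log2(FPKM + 1) scale, 4 belonged to the list of the unfolded protein and integrated stress response. This is the programme cells switch on when amino acids or protein folding fall short. *Chac1*, which encodes a glutathione-degrading enzyme (ENSMUSG00000027313, chromosome 2, 119351229 to 119354381), rose 18.5-fold, from 2.26 ± 0.0927 to 41.9 ± 1.57 FPKM (SD, n = 3 each; log2 fold change 3.72 ± 0.06 SE, limma adjusted p = 6.42e-06). *Asns*, asparagine synthetase (ENSMUSG00000029752, chromosome 6, 7675169 to 7693254), rose 8.05-fold, from 11.4 ± 0.844 to 91.9 ± 1.77 FPKM (limma adjusted p = 1.75e-05). The pseudokinase gene *Trib3* (chromosome 2, 152337422 to 152344032) rose 9.85-fold to 27.5 ± 3.02 FPKM, and the stress sensor gene *Sesn2* (chromosome 4, 132492032 to 132510501) rose 5.57-fold to 64.7 ± 3.72 FPKM. The amino acid transporter genes *Slc7a5* and *Slc7a1* rose 5.35-fold and 3.96-fold. *Mthfd2*, of mitochondrial one-carbon metabolism, and *Aldh18a1*, of proline synthesis, rose 3.86-fold and 5.50-fold. Among the 12 there were also the water and glycerol channel gene *Aqp9* (9.59-fold), *Cyb5r1* (5.27-fold) and *Tmem119* (4.73-fold). In the list of the unfolded protein and integrated stress response, 12 of 24 tested members rose and 4 fell (12 and 5 adjusted over the list alone), and the list was called as higher (camera, adjusted p = 0.00334). The list's adjusted p was 0.326 with an estimated correlation and 0.0616 with quantile normalization. The 4 that fell were *Dnajb9*, *Manf*, *Pdia4* and *Creld2*, named after their values were seen, which belong to protein folding in the endoplasmic reticulum.

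B cell genes fell most. All 15 tested B cell markers were lower in KO, also when adjusted over the list alone, and 10 of the 12 largest falls were immunoglobulin genes. The immunoglobulin heavy chain gene *Ighm* (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730) was 25.6-fold lower, at 271 ± 31.5 FPKM in WT and 10.6 ± 1.85 FPKM in KO (SD, n = 3 each; log2 fold change -4.56 ± 0.14 SE, limma adjusted p = 2.97e-05). The B cell receptor component genes *Cd79b* (chromosome 11, 106311341 to 106314762) and *Cd79a* (chromosome 7, 24897381 to 24902197) were 21.7-fold and 15.3-fold lower, and the light chain gene *Igkc* was 23.8-fold lower. The variable segments *Ighv11-2* and *Igkv14-126* were 92.1-fold and 85.1-fold lower, resting on 5 and 10 reads over the KO libraries. The joining segment *Igkj4* had 42 reads over the WT libraries and 0 over the KO libraries, at least 14.0-fold lower with a floor of 3 reads over the group. The B cell attractant *Cxcl13* (34.6-fold lower, 57.8 ± 8.50 to 1.67 ± 0.477 FPKM) and *Ly6d* (34.1-fold lower) completed the 12. Immunoglobulin segments are close copies of each other, so reads may be divided between them. The list was called as lower (camera, adjusted p = 1.39e-16), with an adjusted p = 0.326 with an estimated correlation.

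Some markers in 5 lists of other cell types were also lower in KO, by smaller amounts. Of the T and NK cell markers 7 of 8 fell, such as *Trbc2* (from 3.72 ± 0.303 to 0.836 ± 0.172 FPKM) and *Lck* (from 3.08 ± 0.609 to 0.612 ± 0.236 FPKM). Of the dendritic cell markers 7 of 10 fell, with the chemokine receptor gene *Ccr7* 4.38-fold, the actin-bundling gene *Fscn1* 5.45-fold and *Ccl22* 4.01-fold lower. *Itgax*, another dendritic cell marker that macrophages also carry, did not pass (limma adjusted p = 0.0634, log2 fold change 0.27). Of the mesothelial and fibroblast markers 4 of 8 fell, among them *Sparc* (2.71-fold) and the collagen gene *Col1a1* (2.59-fold), both at low levels in WT (6.51 ± 0.433 and 4.10 ± 0.497 FPKM). Of the mast cell and basophil markers 4 of 6 fell, including *Cma1* and *Tpsb2*, at 1.93 ± 0.246 and 2.47 ± 0.562 FPKM in WT. Of the neutrophil markers 4 of 13 fell, including *Il1r2* (3.14-fold), *Mmp8* (2.41-fold) and *S100a8* (2.03-fold), while *S100a9* stood at 297 ± 70.2 FPKM in WT and 304 ± 24.2 FPKM in KO. Adjusted over each list alone, 7, 7, 5, 4 and 4 members fell in these 5 lists, in the order given, and 1 dendritic cell marker rose. All 5 lists were called as lower (camera, adjusted p = 1.01e-04, 0.00131, 2.36e-04, 0.00401 and 0.0203 in the same order), with adjusted p = 0.326, 0.48, 0.326, 0.326 and 0.495 with an estimated correlation. The dendritic cell call was lost at a mean of at least 2 FPKM (adjusted p = 0.0689), and the neutrophil call was lost without WT replicate 3 (adjusted p = 0.0725).

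Interferon-inducible genes were lower in KO. In the list of interferon-gamma-type GTPases and IRF1 targets, 15 of 20 tested members fell and 0 rose (19 fell adjusted over the list alone). The GTPase gene *Iigp1* (chromosome 18, 60376029 to 60392627) fell from 7.79 ± 1.29 to 0.0553 ± 0.0639 FPKM (SD, n = 3 each; log2 fold change -3.05 ± 0.12 SE, limma adjusted p = 6.70e-05). Its KO value rests on 7 reads over the libraries (0.125, 0.0406 and 0 FPKM in KO replicates 1 to 3), too few for a stable fold. *Psmb9*, an immunoproteasome subunit gene, was 5.20-fold lower and *Ciita*, the master regulator of MHC class II genes, was 7.34-fold lower. Among type I interferon-stimulated genes, 20 of 33 fell and 0 rose (29 fell adjusted over the list alone). The antiviral gene *Rsad2* was 3.93-fold lower (40.1 ± 9.35 to 10.2 ± 5.60 FPKM, limma adjusted p = 0.0102), *Cmpk2* 4.07-fold and *Isg20* 2.12-fold. *Ifit3*, which shares reads with its near copy *Ifit3b*, was 9.69-fold lower, and 16.4-fold without KO replicate 1. The replicate 1 libraries stood apart in both lists. The median type I member was at 68.6%, 118% and 116% of the WT mean in WT replicates 1 to 3 and at 58.2%, 26.1% and 23.0% in KO replicates 1 to 3. The median interferon-gamma member was at 77.5%, 116% and 109% in WT and at 50.4%, 19.5% and 16.1% in KO. The interferon genes *Ifng* and *Ifnb1*, chosen after their values were seen, did not pass (limma adjusted p = 0.845 and 0.902) and were highest in KO replicate 1, at 3.14 and 1.88 FPKM, and lowest among the WT libraries in WT replicate 1, at 0.145 and 0 FPKM. Both lists were called as lower (camera, adjusted p = 1.86e-09 and 2.46e-09), with adjusted p = 0.494 and 0.667 with an estimated correlation. The type I list was also not called by fry (adjusted p = 0.0793). In the same libraries the median B cell marker had a log2 KO/WT ratio of mean FPKM of -4.44, against -1.84 and -1.39 for these 2 lists.

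Antigen presentation genes went both ways. Of 17 tested members 8 fell and 2 rose (the same counts adjusted over the list alone). The peptide transporter genes *Tap1* and *Tap2* were 3.79-fold and 2.05-fold lower, while the co-stimulatory gene *Cd80* rose 1.92-fold, from 20.8 ± 3.98 to 39.8 ± 4.02 FPKM (limma adjusted p = 0.0079). The list was called as lower (camera, adjusted p = 0.0412), with adjusted p = 0.785 with an estimated correlation. The call was lost without WT replicate 2 (adjusted p = 0.0524), WT replicate 3 (0.0727), KO replicate 2 (0.073) or KO replicate 3 (0.0752). B cells, whose markers fell, also carry several of these genes.

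Most lysosome genes, and 10 of 19 genes of alternatively activated macrophages, were higher in KO. *Chil3* (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), a chitinase-like gene of alternatively activated macrophages with near-identical copies that may share its reads, rose 4.27-fold, from 895 ± 62.9 to 3827 ± 238 FPKM (SD, n = 3 each; log2 fold change 2.10 ± 0.11 SE, limma adjusted p = 1.70e-04). *Retnla* rose 3.35-fold, from 76.5 ± 6.20 to 256 ± 6.56 FPKM, the lectin gene *Mgl2* 2.88-fold and the fibronectin gene *Fn1* 2.66-fold. Of the 19 tested members of the alternative activation list 10 rose and 4 fell (11 and 4 adjusted over the list alone). The 4 that fell were *Ccl22*, *Ccl17*, *Irf4* and *Socs2*; *Irf4* and *Socs2* are named after their values were seen. The list's adjusted p was 0.014 with camera, 0.326 with an estimated correlation and 0.0616 with quantile normalization. Of 32 lysosome genes 27 rose and 1, the transcription factor gene *Tfeb* (named after its value was seen), fell (28 and 1 adjusted over the list alone). The hydrolase genes *Gusb* and *Ctsa* rose 1.85-fold and 1.68-fold, with *Ctsa* going from 143 ± 7.91 to 240.0 ± 2.14 FPKM (limma adjusted p = 0.00127). The lysosome list had an adjusted p = 2.68e-09 with camera and an adjusted p = 0.495 with an estimated correlation. In these libraries 5 of 13 pan-macrophage markers rose and 1 fell (8 and 2 adjusted over the list alone), with a median log2 fold change of 0.40, and that list did not pass with camera (adjusted p = 0.0679; 0.495 with an estimated correlation) but was called as higher by fry (adjusted p = 0.012).

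Part of the autophagy, glycolysis and hypoxia genes rose, by smaller amounts. Of 25 autophagy genes 8 rose and 0 fell (10 and 1 adjusted over the list alone), among them *Atg12* (1.64-fold) and *Atg5* (1.56-fold). Of 31 glycolysis and hypoxia genes 16 rose and 1 fell (the same counts adjusted over the list alone). *Ero1l* rose 1.98-fold and *Ndrg1* 1.66-fold, and the member that fell was *Adm*, which encodes the peptide hormone adrenomedullin (6.03-fold lower). Of 31 genes of oxidative phosphorylation 7 rose and 1, *Ndufa4*, fell from 11.7 ± 1.32 to 6.55 ± 0.689 FPKM (5 and 1 adjusted over the list alone). The 3 lists were called as higher (camera, adjusted p = 0.0139, 9.17e-04 and 0.0339), with adjusted p = 0.494, 0.495 and 0.495 with an estimated correlation. Quantile normalization ended each call (adjusted p = 0.11, 0.156 and 0.695 in that order), and the last was also lost without WT replicate 2 (adjusted p = 0.0878), KO replicate 1 (0.0607) or both replicate 1 libraries (0.0541), at a mean of at least 2 FPKM (0.164), and with median-of-ratios factors (0.0626), TPM (0.0853, and 0.155 over the same genes) or array weights (0.0584).

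Heat shock genes were lower in KO. Of 14 tested members 9 fell and 0 rose (12 fell adjusted over the list alone). The chaperone genes *Hspa1b* and *Hspa1a*, near-identical neighbours on chromosome 17 that share reads, were 6.13-fold and 5.70-fold lower (*Hspa1b* 129.8 ± 26.0 to 21.2 ± 3.16 FPKM, SD, n = 3 each; limma adjusted p = 3.55e-04). *Hspb1* was 2.74-fold and *Hsph1* 1.72-fold lower. The list had an adjusted p = 1.38e-06 with camera and an adjusted p = 0.326 with an estimated correlation. Cytosolic ribosomal protein genes, a check on RNA quality, were called as slightly lower (median log2 fold change -0.14, camera adjusted p = 0.00131), with 3 of 35 members called and 0 adjusted over the list alone. The adjusted p of that list was 0.785 with an estimated correlation and 0.14 with fry, and *Rplp1* stood at 854 ± 45.6 FPKM in WT and 813 ± 45.0 FPKM in KO. None of 12 mitochondrially encoded genes was called (limma; list adjusted p = 0.175 with camera).

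**Figure D3:**
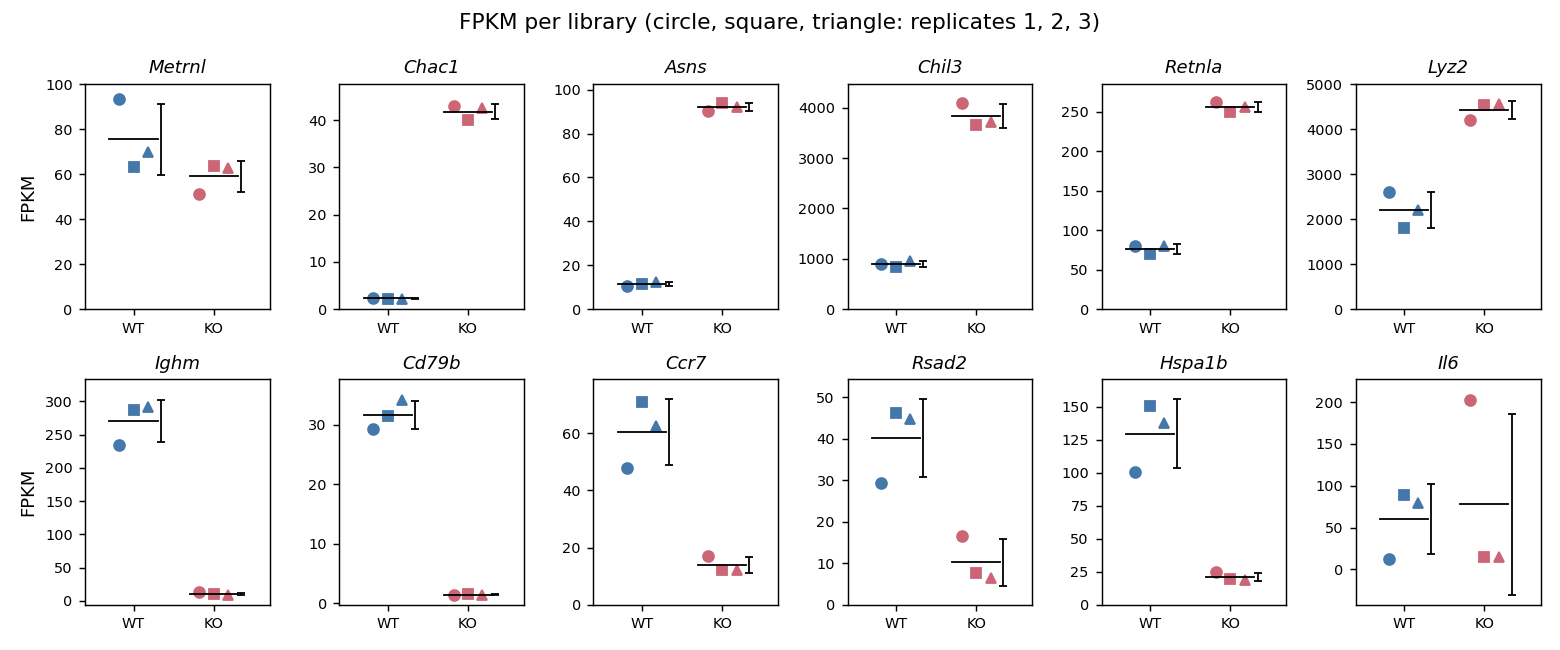
FPKM per library of 12 genes, WT in blue and KO in red, with circles, squares and triangles for replicates 1, 2 and 3. Horizontal lines are group means and vertical bars the SD (n = 3 each); *Metrnl* overlaps between the groups, *Chac1* and *Ighm* are far apart, and the *Il6* values of KO replicate 1 and WT replicate 1 lie on opposite sides of the other libraries of their groups.

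**Figure D4:**
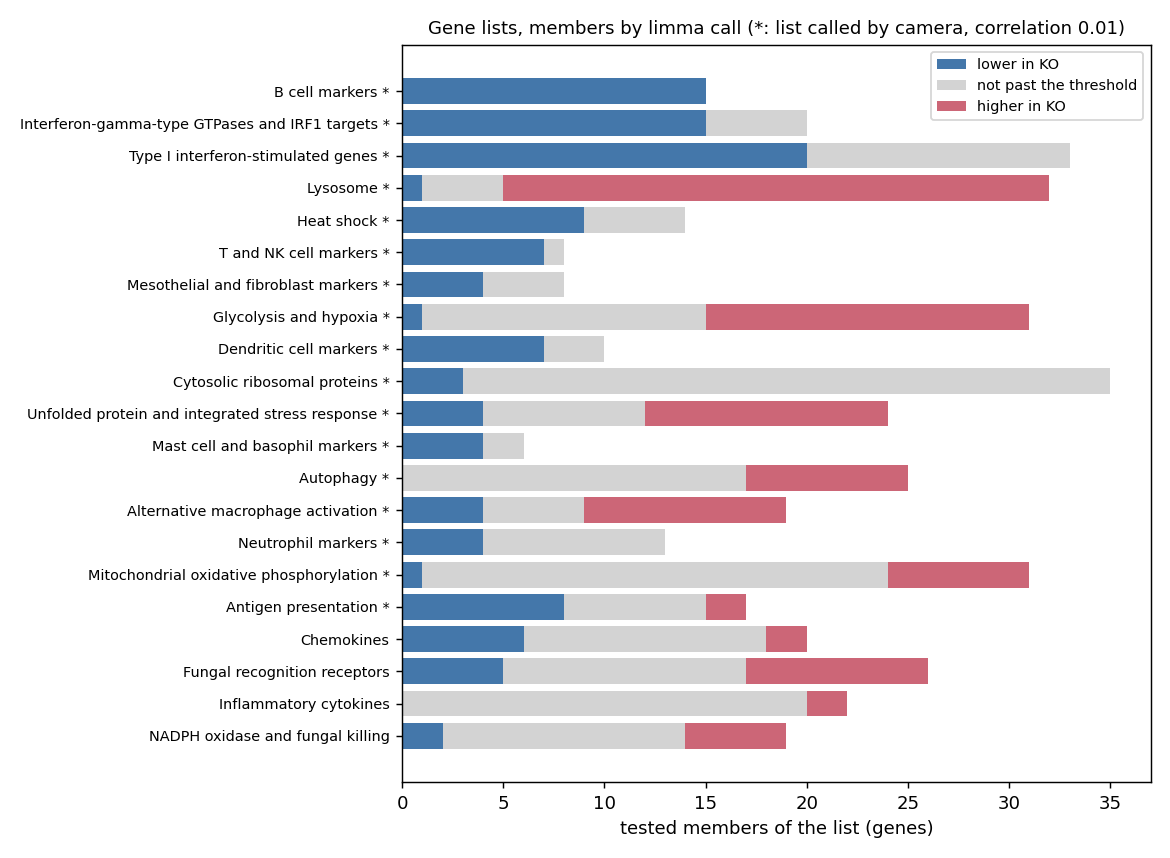
Tested members of 21 gene lists by their limma call, lower in KO (blue), not past the threshold (grey) and higher in KO (red). An asterisk marks the 17 lists called by camera with a preset correlation; all 15 B cell markers are lower and 27 of 32 lysosome genes are higher.

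The genes that sense and kill fungi, which the infection makes of direct interest, were not called as groups. Of 26 fungal recognition receptor genes 9 rose and 5 fell (10 and 5 adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.336; 0.0496 as higher with no filter on low values). The Toll-like receptor genes *Tlr4* and *Tlr7* rose 2.69-fold and 1.65-fold, *Cd5l* rose 2.09-fold and *Tlr9*, which B cells also express, was 2.56-fold lower (9.28 ± 0.737 to 3.62 ± 0.761 FPKM). *Clec7a*, the gene of the beta-glucan receptor dectin-1, named after its value was seen, had an adjusted p = 0.353 with limma. Of 19 genes of the NADPH oxidase and fungal killing 5 rose and 2 fell (6 and 4 adjusted over the list alone; camera, adjusted p = 0.902). The oxidase subunit gene *Cyba* rose 1.62-fold, the proton channel gene *Hvcn1* 1.55-fold and the lysozyme gene *Lyz2* 2.01-fold, to 4431 ± 203 FPKM, a call lost with no filter (adjusted p = 0.07).

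Inflammatory cytokine genes were not called as a group. Of 22 tested, 2 rose and 0 fell (the same counts adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.78). *Osm*, oncostatin M, rose 1.94-fold, from 154 ± 31.3 to 299 ± 45.5 FPKM (limma adjusted p = 0.0124). *Inhba*, an activin subunit gene, rose 1.32-fold (limma adjusted p = 0.0189), a call lost without KO replicate 2 (adjusted p = 0.0812) or KO replicate 3 (0.0766) and with TPM (0.134), quantile normalization (0.119) or no filter (0.0819). *Il1f9* had a lower mean in KO, 375 ± 97.4 against 216 ± 75.8 FPKM, and did not pass (limma adjusted p = 0.087), but was called as lower without WT replicate 1 (adjusted p = 0.0427) or KO replicate 1 (0.0283). *Il6*, chosen after its values were seen, stood at 12.5, 89.0 and 80.1 FPKM in WT replicates 1 to 3 and at 203, 15.4 and 14.9 FPKM in KO replicates 1 to 3. With both replicate 1 libraries left out, the cytokine list was called as lower in KO (camera, adjusted p = 2.36e-05), an alternative chosen after seeing the data. For most of these cytokines the 2 libraries left out lay nearer to the other group, so leaving them out favoured such a call. The libraries that remained were also the most alike pairs of their groups. That call is therefore no support for lower cytokine RNA in KO, and the chemokine call without both, below, rests on the same pairs. Of 20 chemokine genes 6 fell and 2 rose (6 and 4 adjusted over the list alone). *Cxcl13*, *Pf4* (2.20-fold), *Ccl22* and *Ccl17* (3.31-fold) were lower. The chemokine list did not pass (camera, adjusted p = 0.0607; 0.785 with an estimated correlation). It was called as lower without WT replicate 1 (adjusted p = 0.0126), KO replicate 1 (0.004) or both (3.68e-05), with no filter (0.0145), a mean of at least 2 FPKM (0.0417), quantile normalization (0.0289), TPM (0.0101, and 0.0284 over the same genes) or array weights (0.00651), and its highest adjusted p over the other alternatives run with camera and the preset correlation was 0.124.

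Of the 43 lists with enough tested members, 17 were called, 6 as higher and 11 as lower in KO, and none held with an estimated correlation (lowest adjusted p = 0.326; 5 lists at an unadjusted p below 0.05). The fry test called 17 lists, 15 of them among those called by camera. The 22 remaining lists that were not called had adjusted p-values from 0.0679 to 0.923. The transcription factor families that the deposited table assigns to genes gave 0 calls among 10 families (camera, 0 at an unadjusted p below 0.05; lowest adjusted p = 0.554). Marker lists with too few tested genes stayed near the floor for erythroid, epithelial and retinal cells, with highest mean levels of 0.035, 0.598 and 0.82 FPKM (*Klf1*, *Cdh1* and *Rom1*). The eosinophil and endothelial lists also had too few tested genes, but reached 48.3 and 3.75 FPKM (*Alox15* and *Vwf*).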

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

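The voom and both-replicate-1 alternatives and TPM of the same genes were chosen after the data were seen. All 3278 called genes that were tested kept their direction in every alternative run. For 3277 of them the groups did not overlap, so leaving out libraries could not turn their direction. The eBayes settings, the replicate block and the filters leave the fold change as it is, so they could not either. The other pseudocount and array weights cannot turn a gene whose groups do not overlap. Only quantile normalization, median-of-ratios factors, TPM and voom could have turned the direction of these genes. The 17 called lists kept their direction wherever they had enough members to be tested. The T and NK cell, mesothelial and fibroblast, and mast cell and basophil lists did not at a mean of at least 2 FPKM. The genes higher and lower in KO numbered 1833 and 1445. A mean of at least 2 FPKM left 876 lower genes, from fewer genes tested. TPM rescaling left 511 higher genes among 15259 tested, and 542 in TPM of the same 11689 genes, so a change of filter is not needed for the lower count. A 2-fold minimum left 126 and 405. Without each replicate in turn the counts were 908 to 1674 higher and 849 to 1353 lower, from fewer libraries. Voom on recovered reads called 1988 and 1576, and 3156 of the 3278 genes were shared. Lists called fell from 17 to 0 with an estimated correlation and were 15 to 25 under the settings with the preset one. *Metrnl* stayed below the threshold in every alternative, with log2 fold changes from -0.48 to -0.07.

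Libraries of the same replicate number did not deviate from their group means in the same direction. Deviations from the group means correlated at -0.50, -0.19 and -0.16 for numbers 1 to 3, and no library correlated best with its own number. With the number as a block 479 genes were higher and 604 lower, 23 named genes and the antigen presentation list (adjusted p = 0.0538) lost their call, 16 lists were called and *Metrnl* had an adjusted p = 0.328.

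Of 106 other named genes 95 were called. Of these, 71 kept their call in every alternative in which they were tested, and 0 reversed. Leaving out libraries could not reverse a gene whose groups do not overlap, nor could the other settings named above as unable to. Values near 0 changed sign. *Gata2* had log2 fold changes of 0.087 with quantile normalization, 0.13 without both replicate 1 libraries and -0.17 to 0.094 without each replicate. *S100a9* had -0.032 with quantile normalization, -0.020 with TPM over either set of genes, -0.0067 with array weights and -0.14 to 0.20 without each replicate, and *Rpl19* -0.050 to 0.020 without each replicate. Of the uncalled lists, the cytokines changed direction with no filter (adjusted p = 0.956) and without WT replicate 3, KO replicate 2 or KO replicate 3 (range without each replicate in turn 0.0874 to 0.947). NADPH oxidase and fungal killing changed direction at 2 FPKM (adjusted p = 0.933), with quantile normalization (0.395), array weights (0.644), without both replicate 1 libraries (0.273) and without either of them (range without each replicate in turn 0.703 to 0.915). The cause was not tested. Apart from voom, tests for read counts were not run, since the table holds FPKM. Depth limits genes with few reads, such as *Igkj4* with 42 in WT.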

Other observations

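The share of genes on which the replicate 1 libraries lie nearer to the other group and the counts over splits were set before their results were seen, and the test of the large peritoneal macrophage list was fixed before the data were examined. All other tests below, the exchanged split as a test of an exchange included, were chosen after the result was seen, and the gene groups of the next paragraph were assembled then.

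Most cytosolic aminoacyl-tRNA synthetase genes, which load tRNA with amino acids, were higher in KO. Of 20 tested cytosolic aminoacyl-tRNA synthetase genes 14 rose, 2 fell (*Vars* and *Kars*) and 4 did not pass (limma), with *Nars* going from 72.5 ± 0.872 to 202 ± 10.1 FPKM, *Gars* from 13.2 ± 0.922 to 41.5 ± 1.87 FPKM and *Yars* from 3.91 ± 0.371 to 14.7 ± 1.18 FPKM (SD, n = 3 each). Of 10 tested mitochondrial synthetases 1 rose and 1 fell. Of 12 amino acid transporter genes 9 rose and 1 fell, with *Slc3a2* at 318 ± 13.1 and 529.5 ± 54.3 FPKM and *Slc1a5* at 18.3 ± 1.67 and 39.4 ± 3.69 FPKM. Of 11 genes of serine, one-carbon and proline synthesis 7 rose and 2 fell, with *Psat1* at 4.64 ± 0.517 and 14.2 ± 1.97 FPKM. The mitochondrial members had a median log2 fold change of -0.016 (quartiles -0.12 to 0.15) against 0.79 (0.11 to 1.29) for the cytosolic ones, and these ranges overlap.

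Markers of large peritoneal macrophages, a resident type, went both ways: 4 of 14 rose and 6 fell (limma), and the list was not called (camera, adjusted p = 0.648). *Timd4* and *Vsig4* had log2 fold changes of -1.84 and -1.10 (limma adjusted p = 0.000958 and 0.00517), and *F5* and *Lbp* had 0.80 and 0.61 (adjusted p = 0.000629 and 0.00365). Genes within 10 Mb of *Metrnl* on chromosome 11 were called about as often as all genes, 39 of 147 or 26.5% against 28.0%.

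*Metrnl* RNA in KO-labelled libraries stood at 78.4% of the WT mean. WT cells mixed in at that share and keeping their WT levels would hold their genes near or above 78.4% of the WT level. The interferon-gamma list, chosen after it was seen to be lower, had a median of 28.0% (quartiles 17.8% to 41.8%). The medians were 50.4%, 19.5% and 16.1% in KO replicates 1 to 3. This argues against such a mixture, but not against one in which interferon-inducible genes of WT cells changed with the culture. The paralogue *Metrn* reached at most 0.0498% of the *Metrnl* level. Its value would also be low if its reads had been counted as *Metrnl*, so it does not decide whether *Metrn* supplied reads. A deletion that leaves most of the transcript may give such a level and stays open, as per-gene values do not show exons. Reads over the targeted exons would decide it.

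B cell and interferon-stimulated genes fell together in KO. A loss of all other cell types by one shared factor is argued against by the unlike falls of their lists. The T and NK cell list had a median log2 ratio of mean FPKM of -1.45 (quartiles -2.05 to -1.23) and the B cell list -4.44 (-4.74 to -3.96). The T and NK cell markers named above stood at low levels, where ratios are less certain. A loss of all these cell types by unequal factors was not tested and stays open. B cells as the only source of the interferon-stimulated transcripts are argued against in the same way, as the type I list had a median of -1.39 (-1.98 to -1.08). Fewer B cells in the KO cultures may still contribute, and an effect of the genotype on macrophages cannot be told apart from the cell mixture in bulk RNA, where pan-macrophage markers had a median log2 fold change of 0.40. No sort or gate is named in the labels.

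Cytokine genes set WT replicate 1 and KO replicate 1 apart. For 20 of 22 cytokines WT replicate 1 lay nearer to KO replicates 2 and 3, and for 18 of 22 KO replicate 1 lay nearer to WT replicates 2 and 3. An exchange of these 2 libraries would do this for most genes called between the other 4 libraries. Of the 4136 such genes among the 11689 tested, it held for 28.0% and 27.2%. Both shares lie just above the bound of 25% set beforehand to exclude an exchange. The split with both exchanged called 122 genes against 3278, which argues against an exchange. That split called 16 lists against 17 with the preset correlation, so the list counts do not part the 2 splits. A batch that shifts both libraries of a replicate number in the same direction is argued against by the correlation of their deviations, -0.50. A batch with opposite effects in the 2 genotypes would give a negative correlation, so the value cannot exclude it. A different strength or timing of stimulation in single cultures may be involved and stays open, as no label records it.

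The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The labelled split called 3278 genes and the highest other 122, and 1 of 10 splits had as many. It called 17 lists and the highest other 16, with 1 of 10 splits having as many. Other splits called 6 to 16 lists, so lists are also called with a preset correlation in splits that mix the genotypes. Each such split holds the genotypes in unequal numbers on its sides, so part of the genotype difference remains in it. Transcription factor families gave 0 calls in all 10 splits.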
